A study of Mus musculus with 8 samples.

How the data were processed

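Basal epidermal cells of CD1 mouse back skin were profiled on Affymetrix arrays, in 3 control mice, 3 mice at day 4 of skin expansion and 2 TPA-treated mice, with 1 array per mouse. Per the labels' protocols, epidermis was separated with trypsin at 4 °C overnight, and 300 ITGA6-positive, CD34-negative cells were sorted per sample. RNA was purified on beads and amplified as cDNA, and amplification was stopped after 25 cycles. The deposited values are log2 signals of RMA, per the submitters' processing notes, which name no version. The table held 45141 probe sets and no column of other samples. Array medians lay between 7.08 and 7.14 and maxima between 13.6 and 13.7. Detection calls, raw scans and scan dates were not used here, so signal cannot be set against background probe by probe. As a stand-in, chosen after the results were seen, the limit was the 95th percentile of 79 olfactory, vomeronasal and trace amine receptor genes on each array, and 32.9% of genes lay under it on every array. A bound is the mean of the brighter group minus that of the dimmer one with its signals raised to the limit. It depends on these genes being silent here. The precision given rests on the number of arrays and on each gene's spread between them, not on the number of cells.

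Of the probe sets, 28898 carried 1 gene symbol in the probe table of the platform, whose annotation dates from 2016, 551 carried several, 15588 carried none and 104 were array controls. Each gene was represented by the probe set with 1 symbol and the highest mean over all arrays, which gave 17097 genes, of which 7180 had more than 1 probe set. The symbols of 209 could not be found by their gene identifier in a current gene table and were kept as they stood. Other probe sets of the same gene were called in the opposite direction for 3, 23 and 1 genes between expanded and control, TPA and control, and expanded and TPA. Areg is not among the named probe sets and was not analysed here. The control probe sets were left out by plan, and their names and values proved to be out of order. Gene rows were checked with 619 pairs of probe sets of the same gene, whose median correlation was 0.93, beside 0.02 with a partner 1 row off and -0.06 with a partner 3 rows off.

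A linear model with 1 coefficient per group was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 residual and 3.54 prior degrees of freedom). Each of the 3 comparisons was adjusted by Benjamini-Hochberg over the genes, with a threshold of 0.05, and 4056, 5412 and 3307 genes lay under an unadjusted p of 0.05. The fit was tested on simulated data with 50 genes changed at each fold. At a fold of 1.5 it recovered 80%, 62% and 60% of the genes changed between expanded and control, TPA and control, and expanded and TPA, and at a fold of 2 it recovered 98%, 96% and 92%, with 7, 13 and 9 false calls. Of 35 gene lists, 34 had at least 5 measured members, and 505 of 558 members were measured. The red blood cell list had too few and was not tested. Lists were tested with camera (preset correlation between genes of 0.01), adjusted over the 34 lists, and also by camera with an estimated correlation and by fry. Camera compares a list with all other genes, and fry asks whether its genes move one way. The median, the mean and the camera direction had the same sign in each called list. On simulated data with 1 list shifted by 0.5, camera called 1 of 34. The genes were drawn independently there, so false calls that come from correlation between genes could not show.

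The groups, the tests, the lists, the rule for naming genes and the alternatives were set before the data were examined. The rule took, for each comparison, the 10 largest rises and the 10 largest falls among genes past the threshold with no overlap between the arrays of the 2 groups and a mean in the higher group above 7.11, the median of all genes. It also took up to 4 members of each list with the smallest p, the gate and basal genes Itga6, Cd34, Krt5 and Krt14, and Krt6a, Krt16, Mki67, Fosl1, Ccn2, Ccn1, Areg, Hbegf and Col17a1. Outside the rule, and chosen after their values were seen, are Ptgs2, Cdh5, Pecam1 and Emcn in single arrays, and the genes lying outside both other groups, with S100a8, Slpi, Sprr2h, Serpinb2, Serpinb3a, Timp3, Fos, Krt10 and Cdkn1a in some comparisons. Odc1 is also outside the rule, and comes from a test of phorbol ester genes picked before their values were seen. Replicate numbers did not pair the control and expanded arrays: residuals of arrays with the same number correlated at r = -0.18 to 0.03, and 0 of 6 arrays correlated best with their own number. The correlation and covariance of the comparisons with control were set beside 100 simulated draws of unchanged groups against the same controls. The alternatives were quantile normalization, centring on the array median, a signal filter, the mean of a gene's probe sets, each probe set by itself, a trended robust eBayes, array weights, only the 2 groups compared, a replicate block, a test against a fold of 1.5, a threshold of 0.10, leaving out each array, and, for the correlation of the treatments, Spearman's rho and the brighter genes alone.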

Results

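Gene expression was measured in basal cells of the back skin epidermis of CD1 mice, an outbred laboratory strain. The cells came from 3 groups of mice. In the expanded group the skin had been stretched by a force and was taken at day 4. In the second group it had been treated with 12-O-tetradecanoylphorbol-13-acetate (TPA), a phorbol ester that activates protein kinase C and is used to make mouse epidermis proliferate and become inflamed. Untreated mice served as the control. The series gives 3 control mice, 3 expanded mice and 2 TPA mice, with 1 array per mouse. For each array 300 cells were sorted on the surface integrin ITGA6 and on the lack of CD34, which marks follicle bulge cells. The gate takes in interfollicular and infundibulum cells. Values are RMA signals on the log2 scale, given as mean ± SD over n = 3 control, 3 expanded or 2 TPA arrays, and differences are log2 differences ± SE. No detection calls were used, so 79 genes of smell, vomeronasal and trace amine receptors stand in for background, with their 95th percentile on each array (6.37 to 6.55) as its limit. Where a group lay under the limit on each of its arrays, the difference is given as a bound counted from the limit ("at least"), and such differences have no place in an order by size. The small number of arrays limits the precision.

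The transcripts of Itga6, Krt5 and Krt14 were well above the background limit in all 3 groups. Krt5 and Krt14, the keratins of basal cells, stood at 13.28 ± 0.05 and 13.30 ± 0.04 in the arrays labelled control. Neither passed the test in any comparison, and the largest difference was that of Krt5 between TPA and control (0.05 ± 0.07). These levels lie close to the highest signal on any array, where differences are compressed. Itga6 was at 12.27 ± 0.04, 11.80 ± 0.04 and 11.58 ± 0.09 in the arrays labelled control, expanded and TPA. Cd34 was at 4.79 ± 0.17, 4.74 ± 0.02 and 4.55 ± 0.07, under the background limit in each group. Col17a1, a hemidesmosome collagen, and Mki67, a proliferation marker, did not pass in any comparison either. Arrays of 1 group correlated across genes at r = 0.990 to 0.995. Control and expanded arrays correlated at 0.980 to 0.982, expanded and TPA arrays at 0.982 to 0.987, and control and TPA arrays at 0.961 to 0.965. The first principal component held 61.1% of the variance and placed the expanded arrays between the other groups. The second held 12.7% and set the expanded arrays apart from both.

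**Figure D1:**
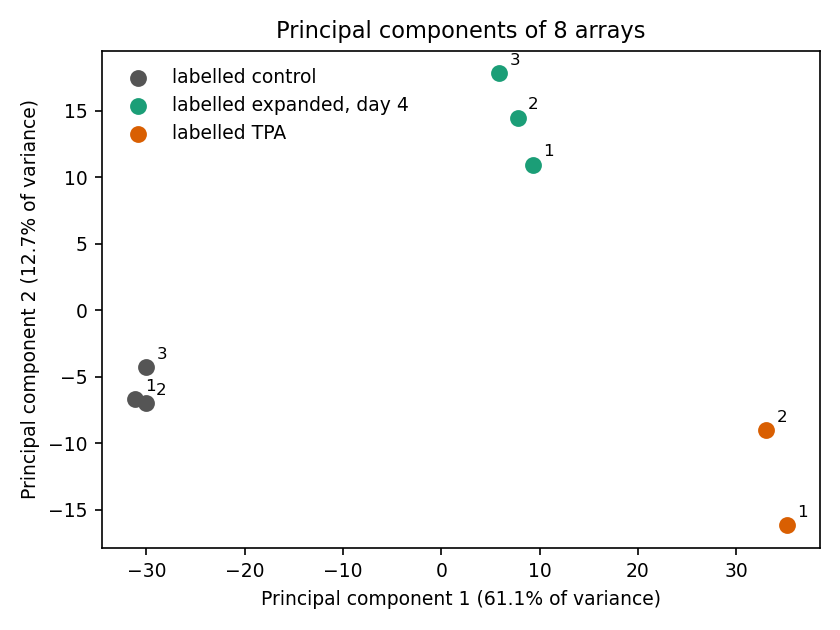
Principal components 1 and 2 (scores, with the percent of variance on each axis) of the 8 arrays over 17097 genes, each point an array, coloured by its label and numbered by replicate. The 3 control arrays lie between -31.2 and -30.0 on component 1, the 3 expanded arrays between 5.88 and 9.35, and the 2 TPA arrays at 33.1 and 35.2.

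The arrays are named here by their labels, because a set of genes tied to phorbol ester treatment and wounding ran against them. Krt6a and Krt16, keratins induced in wounded and hyperproliferative epidermis, were lowest in the arrays labelled TPA. Krt6a was at 13.23 ± 0.06 in the control arrays, 13.14 ± 0.02 in the expanded arrays and 12.54 ± 0.15 in the TPA arrays, and Krt16 at 13.04 ± 0.01, 12.90 ± 0.04 and 12.15 ± 0.07. Of the 14 measured stress and wound genes, 11 had their highest mean in the control arrays and their lowest in the TPA arrays. Odc1, a gene known for its induction by TPA, showed the same order, with 11.34 ± 0.02, 9.84 ± 0.14 and 8.99 ± 0.09. Each direction below follows the labels as given. If the labels of control and TPA were exchanged, the comparison of TPA with control would turn, and the comparisons of expanded with control and with TPA would trade places.

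**Figure D2:**
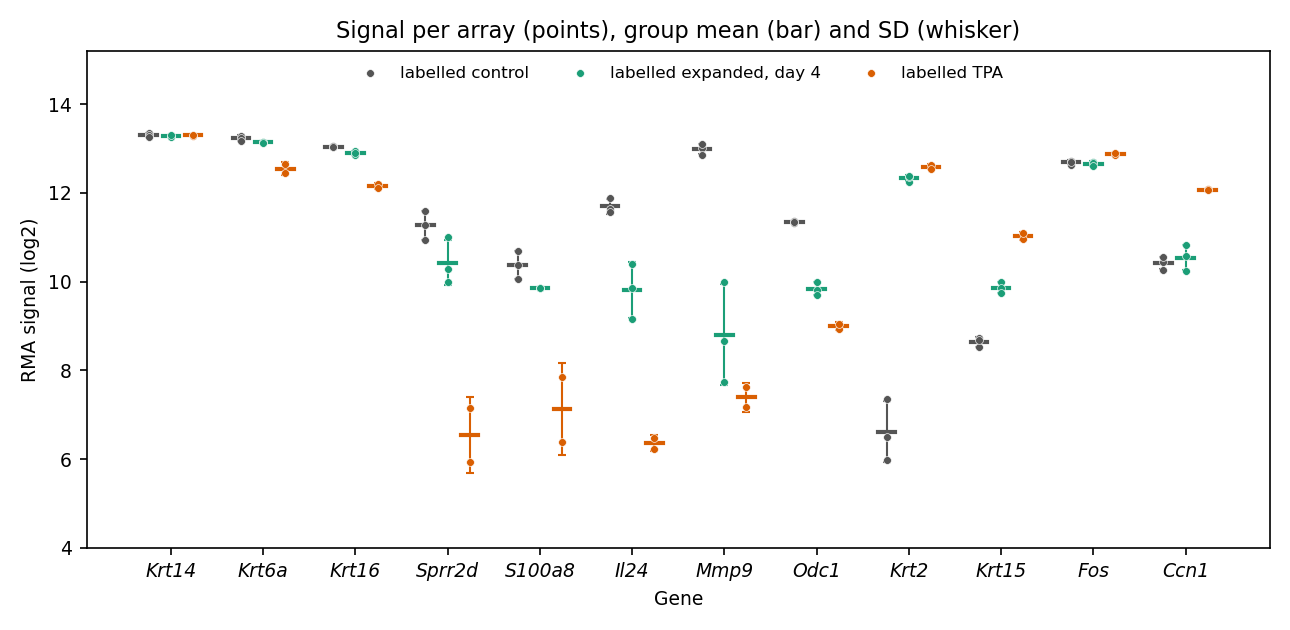
RMA signal (log2) of 12 genes on each array (points), with the group mean (bar) and SD (whisker), for the arrays labelled control (n = 3), expanded (n = 3) and TPA (n = 2). Krt14 is level over the groups, while Krt6a, Krt16, Sprr2d, S100a8, Il24, Mmp9 and Odc1 are lowest in the arrays labelled TPA, and Krt2 and Krt15 are lowest in those labelled control. The genes were chosen for display after their values were seen.

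The comparison of expanded with control asks how basal cells differ 4 days into stretch. Keratins were among the transcripts with the largest differences. Krt2, a keratin of the differentiated interfollicular epidermis, was higher in the arrays labelled expanded (5.72 ± 0.28, adjusted p = 2.87e-05). It stood at 12.33 ± 0.07 there and at 6.61 ± 0.69 in control arrays, above the background limit on 2 of 3. Krt36 (4.51 ± 0.20) and Krt84 (3.88 ± 0.18), keratins of hard epithelial structures, were also higher, as was Mt4 (3.29 ± 0.36), the metallothionein of stratified epithelia. Certain matrix proteases and 1 of their inhibitors were among the large falls. Mmp9 (gelatinase) differed by -4.19 ± 0.46 (adjusted p = 0.000823), Mmp13 (collagenase) by -3.83 ± 0.47 and Timp1, an inhibitor of such proteases, by -3.09 ± 0.26.

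In all, 1960 of 17097 genes passed the threshold, 972 higher and 988 lower in the expanded arrays, and 323 of them differed by 2-fold or more (115 higher, 208 lower). Of the 1960 genes, 177 lay under the background limit in the dimmer group, 82 of them in both groups. Other large rises were those of Selenbp2 (2.68 ± 0.26), Fcgbp (2.29 ± 0.13) and Parp10 (2.20 ± 0.17). Efemp1 (at least 1.46), which encodes a matrix glycoprotein, Serpinb7 (at least 0.93), a protease inhibitor, and Maob (at least 0.74), monoamine oxidase B, were higher as well. Other large falls were those of Arg1 (-4.04 ± 0.20), arginase, Neu2 (-3.84 ± 0.29), a sialidase, Fn1 (-3.03 ± 0.77), fibronectin, Uox (-2.83 ± 0.27), urate oxidase, Mal (-2.81 ± 0.14), Inhba (-2.76 ± 0.20), the activin A subunit, and AU018091 (-2.60 ± 0.26). The dimmer group was above the limit on only some of its arrays for Selenbp2 (2 of 3), Arg1 (2 of 3), Neu2 (1 of 3) and Fn1 (1 of 3). Of these genes Fn1 lost its call in 4 of the 8 fits that left out 1 array (without control replicate 1 or 3 or expanded replicate 1 or 3), with adjusted p up to 0.116. Control replicate 1 had the highest Fn1 signal, 11.42 against 8.16 and 9.17 in the other control arrays, and was also highest among them for the endothelial markers Cdh5 (9.73 against 7.02 and 6.86), Pecam1 (8.30 against 6.88 and 6.96) and Emcn (8.14 against 5.75 and 6.34). The expanded arrays are not given one by one for these markers. Between the groups Cdh5 (adjusted p = 0.977) and Emcn (-0.34 ± 0.52, adjusted p = 0.789) did not pass the test. A test of group means cannot show whether their signal was confined to a control array. Emcn was above the background limit on 1 of 3 expanded arrays. Without control replicate 2 the count of genes was 1261, and a test against a fold of 1.5 left 173.

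Of 34 gene lists, 13 were shifted between expanded and control arrays, 2 higher and 11 lower. These are calls of limma's camera with a preset correlation between genes. With an estimated correlation camera called 0 lists (6 at an unadjusted p under 0.05), and that adjusted p is given for each list. limma's fry called 15. Genes of the actin cytoskeleton that SRF and its cofactor MAL control were lower: of 20 measured members 0 were higher and 14 lower (0 and 16 adjusted over the list alone), with a median of -0.63 (adjusted p = 2.02e-12). This cofactor is not the product of the gene Mal named above. Acta2 (-1.44 ± 0.10), Actn1 (-0.91 ± 0.07) and Flna (-0.63 ± 0.07) were among them. In the matrix list, of 22 measured members 1 was higher and 14 lower (2 and 16 adjusted over the list alone), with a median of -0.78 (adjusted p = 2.9e-11). Integrin subunit Itgb6 (-1.47 ± 0.10), the protease Mmp3 (-1.95 ± 0.14) and the urokinase receptor Plaur (-1.45 ± 0.11) were lower. Among EGFR ligands and MAPK feedback genes, of 18 measured members 1 was higher and 7 lower (1 and 11 adjusted over the list alone), with a median of -0.55 (adjusted p = 1.43e-05). The ligands Ereg (at least 1.55), Tgfa (-2.10 ± 0.18) and Hbegf (-0.96 ± 0.09) were lower. In the unfolded protein response list, of 16 measured members 0 were higher and 10 lower (0 and 13 adjusted over the list alone), with a median of -0.40 (adjusted p = 5.77e-08), Trib3 at -1.22 ± 0.09 and the chaperone Hspa5 at -0.55 ± 0.08. For these 4 lists the adjusted p was 0.0758 with an estimated correlation.

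Genes of glycolysis and hypoxia were lower in the expanded arrays, with a median of -0.31 (adjusted p = 2.9e-11): of 17 measured members 0 were higher and 10 lower (0 and 14 adjusted over the list alone). Car9 (-1.76 ± 0.08), Ndrg1 (-1.51 ± 0.07) and Vegfa (-1.23 ± 0.13), all known hypoxia targets, had the largest differences. Cytokines and chemokines had a median of -0.36 (adjusted p = 7.21e-05), and of 22 measured members 0 were higher and 5 lower (0 and 5 adjusted over the list alone). The 5 were Il1a, under the background limit in both groups, Il24 (-1.89 ± 0.27), Il33 (-0.94 ± 0.15), Tnf (-0.82 ± 0.14, above the limit on 1 of 3 expanded arrays) and Ptgs2 (-1.33 ± 0.30), the inducible prostaglandin synthase. With signals raised to the limit the median was -0.10, as 9 members lay under it in both groups. With an estimated correlation the adjusted p of both lists was 0.196. The macrophage and neutrophil markers had a median of -0.34 (adjusted p = 0.0246, and adjusted p = 0.428 with an estimated correlation). Here of 10 measured members 0 were higher and 2 lower (0 and 2 adjusted over the list alone). Cd14 was lower (at least 0.48), and Cxcr2 lay under the background limit in both groups, as did 6 of the 10 members. Lyz2, an abundant myeloid transcript, did not pass (adjusted p = 0.118). With signals raised to the limit the list median was -0.05. Without control replicate 3 or expanded replicate 2 this list did not pass (adjusted p up to 0.0817, median -0.18 without control replicate 3), nor did it with limma's fry.

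Cholesterol synthesis genes had a median of -0.49 (adjusted p = 2.94e-06, and of 14 measured members 0 were higher and 6 lower (0 and 9 adjusted over the list alone)), with Cyp51 at -0.52 ± 0.09 and Fdps at -0.63 ± 0.12. The stress and wound genes had a median of -0.51 (adjusted p = 0.0108), and of 14 measured members 1 was higher and 4 lower (1 and 5 adjusted over the list alone). Sprr1a (-1.57 ± 0.28) and Sprr2h (-1.05 ± 0.24), cornified envelope precursors, were lower, and Serpinb3a (1.93 ± 0.16) was higher. Krt6a and Krt16 did not pass (-0.09 ± 0.08 and -0.14 ± 0.06). Clock genes were higher, with a median of 0.21 (adjusted p = 0.0334): of 15 measured members 4 were higher and 0 lower (4 and 0 adjusted over the list alone), Hlf (0.89 ± 0.13) and Per1 (0.50 ± 0.08) among them. For these 3 lists the adjusted p was 0.244 with an estimated correlation. The clock list did not pass without control replicate 1 or 3 or expanded replicate 2 (adjusted p up to 0.0872).

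In the basal and hemidesmosome list the members went both ways. There of 15 measured members 2 were higher and 8 lower (2 and 8 adjusted over the list alone), with a median of -0.31 (adjusted p = 0.000331, and adjusted p = 0.274 with an estimated correlation). The laminin chains Lamb3 (-0.96 ± 0.07) and Lama3 (-0.92 ± 0.08) and integrin Itgb1 (-0.88 ± 0.07) were lower, while the basal keratin Krt15 (1.23 ± 0.09) was higher. Ribosome biogenesis genes were slightly higher, with a median of 0.23 (adjusted p = 2.18e-05, and adjusted p = 0.307 with an estimated correlation), and of 18 measured members 3 were higher and 0 lower (9 and 0 adjusted over the list alone). Polr1b, a subunit of RNA polymerase I, was at 0.61 ± 0.11. Mitosis genes had a median of -0.22 (adjusted p = 0.000772, and adjusted p = 0.499 with an estimated correlation), but of 21 measured members 0 were higher and 2 lower (0 and 3 adjusted over the list alone), and the list did not pass without control replicate 1 (adjusted p = 0.0689) or with fry, and had a median of -0.14 without expanded replicate 2. The other 21 lists did not pass (lowest adjusted p = 0.0735). Among them, suprabasal genes had a median of 0.16, and of 18 measured members 7 were higher and 3 lower (7 and 4 adjusted over the list alone). With signals raised to the background limit the suprabasal median was -0.05, as 3 members lay under it in both groups. Krt10 (1.47 ± 0.23) and Dsg1a (1.79 ± 0.12) were higher and Cnfn (-1.64 ± 0.10) was lower. The 8 lists of other cell types that did not pass (pigment, Langerhans, T, Merkel and endothelial cells, fibroblasts, bulge and sebaceous gland) had medians from -0.24 to 0.08. Of their members, 6 of 10 for pigment cells, 7 of 11 for T cells and 6 of 9 for Merkel cells lay under the background limit in both groups. The medians of these 3 lists cannot show whether the cells changed. Single members of the 8 lists moved, as H2-Ab1 of antigen-presenting cells did (-1.93 ± 0.38, above the limit on 2 of 3 expanded arrays). Thy1 of the T cell list was higher (1.23 ± 0.13). The other 10 members of that list did not pass, so Thy1 does not show a change in T cells.

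**Figure D3:**
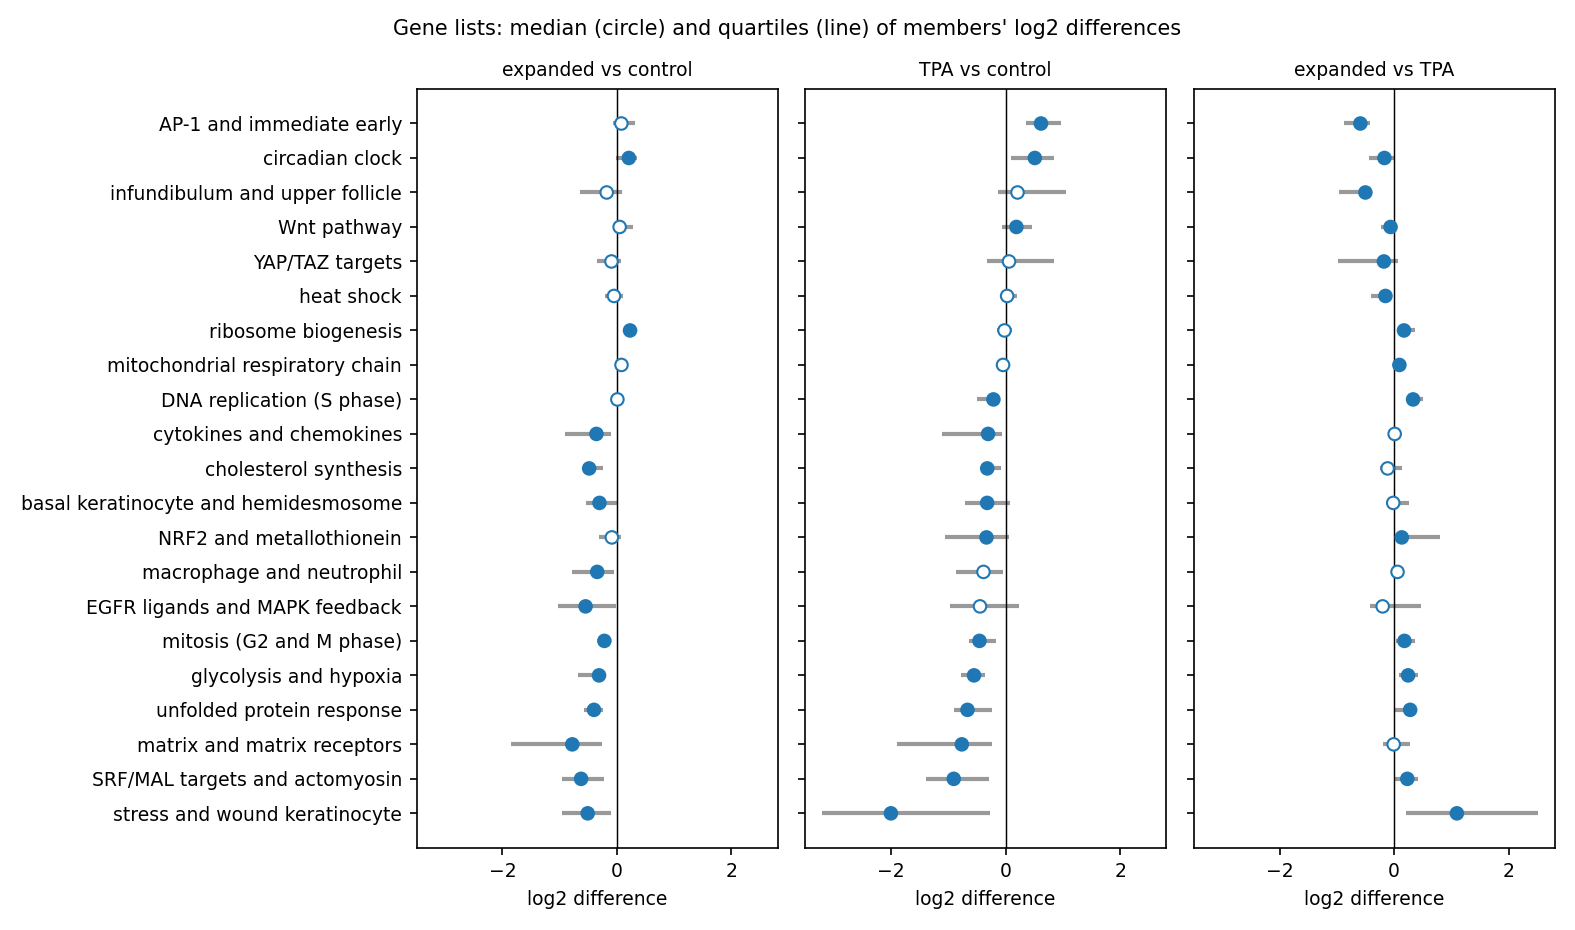
Median (circle) and quartiles (line) of the log2 differences of the members of each gene list, in 3 panels, one per comparison, with the lists called in any comparison in rows. Filled circles mark calls by limma's camera with a preset correlation, none of which passed with an estimated correlation. The stress and wound list has the lowest median between TPA and control, -2.00, and the AP-1 list the highest, 0.62.

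The comparison of TPA with control asks how the same cells differ after phorbol ester. The keratins Krt2 (5.97 ± 0.31, adjusted p = 7.22e-06), Krt36 (4.82 ± 0.23) and Krt84 (4.15 ± 0.20) were again among the most increased transcripts, now in the arrays labelled TPA. Among the large falls were Il24, a cytokine of the IL-10 family (at least 5.22, adjusted p = 1.11e-05), and Mmp9 (-5.60 ± 0.52, adjusted p = 0.000133). Inhba differed by -5.17 ± 0.23, and the cornified envelope precursors Sprr2d and Sprr2h by -4.72 ± 0.39 and -4.27 ± 0.26. The immediate early gene Nr4a1, which encodes a nuclear receptor, was higher (2.53 ± 0.21, adjusted p = 8.33e-05).

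The threshold was passed by 3559 genes, 1744 higher and 1815 lower in the TPA arrays, of which 809 differed by 2-fold or more (371 higher, 438 lower). Of the 3559 genes, 475 lay under the background limit in the dimmer group, 200 of them in both groups. Other large rises were those of Fcgbp (3.79 ± 0.14), Gpha2 (3.54 ± 0.25), Mt4 (3.53 ± 0.40) and Selenbp2 (3.23 ± 0.29). Serpinb7 (at least 2.48), Tmem45a2 (at least 1.64) and Efemp1 (at least 2.62) were higher too, from control signals under the limit. Sh2d5 (at least 4.75), Neu2 (at least 3.25), Uox (at least 4.15), Tubb3 (at least 3.80), a beta tubulin best known from neurons, and Arg1 (at least 4.09) were lower, with TPA signals under the limit. The dimmer group was above it on only some of its arrays for Krt2 (2 of 3), Selenbp2 (2 of 3), Inhba (1 of 2) and Sprr2d (1 of 2). Ccn1, a YAP/TAZ target, was higher (1.65 ± 0.16, adjusted p = 0.00015), and its relative Ccn2, under the background limit in the control arrays, did not pass (adjusted p = 0.106). Hbegf was lower (-0.78 ± 0.10). Fosl1, an AP-1 subunit, was at 0.50 ± 0.14 (adjusted p = 0.0326), and lost its call in 6 of the 8 fits that left out 1 array (without any of the control or TPA arrays or expanded replicate 1), with adjusted p up to 0.136. A test against a fold of 1.5 left 596 genes.

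Of the 34 lists, 14 were shifted between TPA and control arrays by limma's camera, 3 higher and 11 lower. With an estimated correlation camera called 0 (8 at an unadjusted p under 0.05), and fry called 20. The stress and wound list had the largest median difference, -2.00 (adjusted p = 0.000158), and of 14 measured members 2 were higher and 10 lower (2 and 10 adjusted over the list alone). S100a8 (-3.25 ± 0.36, above the background limit on 1 of 2 TPA arrays), a subunit of calprotectin, Slpi (-3.09 ± 0.44), Krt16 (-0.89 ± 0.07) and Krt6a (-0.69 ± 0.09) were lower. Serpinb2 (1.28 ± 0.20) and Serpinb3a (1.04 ± 0.18) were the 2 higher ones. AP-1 and immediate early genes moved the other way, with a median of 0.62 (adjusted p = 4.52e-10), and of 20 measured members 14 were higher and 0 lower (15 and 0 adjusted over the list alone). Jun (1.20 ± 0.12), Btg2 (1.51 ± 0.15) and Myc (0.95 ± 0.08) were higher, whereas Fos was at 0.19 ± 0.07 (adjusted p = 0.118). Among heat shock genes, markers of cell stress and handling, of 8 measured members 2 were higher and 0 lower (2 and 0 adjusted over the list alone), with Hspa1b (0.98 ± 0.08) and Dnajb1 (0.41 ± 0.07) higher. Their list had a median of 0.03 and passed with fry (adjusted p = 0.00348) but not with camera (adjusted p = 0.222, and adjusted p = 0.465 with an estimated correlation). Clock genes were higher as well, with a median of 0.51 (adjusted p = 0.000104), and of 15 measured members 8 were higher and 0 lower (9 and 0 adjusted over the list alone). Those higher included Arntl (1.32 ± 0.13), the gene of the clock activator BMAL1, and its repressor Per1 (0.94 ± 0.09). The adjusted p of the stress and wound, AP-1 and clock lists was 0.13 with an estimated correlation.

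Glycolysis and hypoxia genes were lower in the TPA arrays, with a median of -0.55 (adjusted p = 3.1e-11), and of 17 measured members 0 were higher and 14 lower (0 and 17 adjusted over the list alone). Car9 (at least 2.75) and Bnip3 (-1.97 ± 0.12) were among the lower ones. SRF/MAL genes had a median of -0.90 (adjusted p = 7.39e-09), and of 20 measured members 2 were higher and 15 lower (2 and 16 adjusted over the list alone), with Cald1 at -3.97 ± 0.29 (above the limit on 1 of 2 TPA arrays) and Actn1 at -2.05 ± 0.08. In the unfolded protein response list, of 16 measured members 1 was higher and 12 lower (1 and 12 adjusted over the list alone), with a median of -0.66 (adjusted p = 3.22e-05) and Trib3 at -2.59 ± 0.10. In the matrix list, of 22 measured members 3 were higher and 13 lower (3 and 14 adjusted over the list alone), with a median of -0.76 (adjusted p = 6.52e-05). Timp1 (at least 3.55) and the fibronectin receptor subunit Itga5 (at least 2.63) were lower, and Timp3 (3.16 ± 0.32) was higher. In the NRF2 list, of 14 measured members 0 were higher and 6 lower (1 and 7 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.00543). The heme oxygenase Hmox1 (-3.10 ± 0.16) and the glutathione transferase Gsta4 (-2.15 ± 0.09) were lower. For these 5 lists the adjusted p was 0.13 with an estimated correlation.

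The mitosis and S phase lists were called lower in the TPA arrays, though 9 of 21 and 14 of 22 members did not pass. Mitosis genes had a median of -0.46 (adjusted p = 0.000636, and adjusted p = 0.478 with an estimated correlation), and of 21 measured members 1 was higher and 11 lower (1 and 12 adjusted over the list alone), with Aurka at -0.67 ± 0.09 and Plk1 at -0.68 ± 0.12. S phase genes had a median of -0.21 (adjusted p = 0.00281, and adjusted p = 0.45 with an estimated correlation), and of 22 measured members 0 were higher and 8 lower (0 and 9 adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 at -1.28 ± 0.08. With signals raised to the background limit the S phase median was -0.15. Under it in both groups lay 3 of the 22 members, 1 of them called lower. Mki67 did not pass (-0.11 ± 0.09, adjusted p = 0.458). In the cytokine list, of 22 measured members 1 was higher and 6 lower (1 and 6 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.0124, and adjusted p = 0.381 with an estimated correlation). Its median was -0.17 without control replicate 1, and -0.03 with signals raised to the background limit, as 9 members lay under it in both groups. Il33 (-1.80 ± 0.17) was lower and Ccl20 (1.35 ± 0.12, above the limit on 1 of 3 control arrays) higher. The macrophage and neutrophil markers had a median of -0.39 and did not pass (adjusted p = 0.118), though Cd14 (at least 0.47) was lower. With signals raised to the limit their median was -0.03, as 6 of the 10 members lay under it in both groups. In the basal list, of 15 measured members 2 were higher and 8 lower (2 and 9 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.0397, and adjusted p = 0.469 with an estimated correlation), with Krt15 at 2.38 ± 0.10 and Lama3 at -1.30 ± 0.09.

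Cholesterol synthesis genes had a median of -0.32 between TPA and control (adjusted p = 0.0145, and adjusted p = 0.465 with an estimated correlation), and of 14 measured members 0 were higher and 5 lower (0 and 5 adjusted over the list alone). Squalene epoxidase, Sqle, was at -1.69 ± 0.13. The Wnt pathway list was called higher, with a median of 0.19 (adjusted p = 0.0462, and adjusted p = 0.344 with an estimated correlation). Of 14 measured members 4 were higher, 0 lower and 10 did not pass (4 and 0 adjusted over the list alone), with Wnt3 at 1.53 ± 0.12. With signals raised to the background limit the Wnt median was -0.01. Single arrays ended the call of 3 lists. The cholesterol list did not pass without TPA replicate 2 (adjusted p = 0.402, median -0.17), the basal list without control replicate 1, expanded replicate 3 or TPA replicate 1 (up to 0.115), and the Wnt list without control replicate 1 or 2, expanded replicate 2 or 3 or TPA replicate 1 (up to 0.0698, median 0.08 without TPA replicate 1). Among the 20 lists that did not pass, suprabasal genes had a median of 0.33 (adjusted p = 0.142), and of 18 measured members 6 were higher and 3 lower (8 and 5 adjusted over the list alone). With signals raised to the background limit the suprabasal median was 0.18. Casp14 (2.28 ± 0.32) and Krt10 (1.46 ± 0.26) were higher and Tgm1 (-2.11 ± 0.20) lower. The 9 lists of other cell types had medians from -0.39 to 0.22, with H2-Ab1 (at least 2.01) lower and Thy1 (1.33 ± 0.14) higher. Under the background limit in both groups lay 6 of 10 pigment cell, 7 of 11 T cell, 6 of 10 macrophage and neutrophil and 6 of 9 Merkel cell members. The medians of these lists cannot show whether the cells changed.

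The comparison of expanded with TPA sets the treated groups against each other, since the control cancels. The labels give a day for the expanded arrays only and no batch, so time and batch were not separated from the treatment. Among the large rises in the arrays labelled expanded were Sprr2d (3.88 ± 0.39, adjusted p = 0.00137), Il24 (at least 3.33) and S100a8 (2.74 ± 0.36). Car2, carbonic anhydrase 2, was 10.1-fold higher (3.34 ± 0.17, adjusted p = 5.16e-05), at 11.43 ± 0.14 against 8.10 ± 0.44. Lower in the expanded arrays were Timp3 (-2.34 ± 0.32), the growth factor Bmp2 (-1.94 ± 0.14, adjusted p = 0.000262) and Nr4a1 (-1.77 ± 0.21).

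Here 1022 genes passed, 541 higher and 481 lower in the expanded arrays, and 190 differed by 2-fold or more (96 higher, 94 lower). Of the 1022 genes, 95 lay under the background limit in the dimmer group, 32 of them in both groups. Other large rises were those of Sh2d5 (at least 3.14), Sprr2h (3.22 ± 0.26), Smim3 (2.89 ± 0.17), the desmosomal cadherin Dsc2 (2.73 ± 0.16), the connexin Gjb2 (2.69 ± 0.12) and 2610528A11Rik (2.67 ± 0.11). Other large falls were those of Tmem45a2 (at least 1.69), Col6a1 (-2.20 ± 0.38), Plagl1 (-2.09 ± 0.50), the protease Adamts9 (-2.02 ± 0.16), Gpha2 (-1.96 ± 0.25), the prostaglandin receptor Ptger4 (at least 1.26) and Serpinb2 (-1.81 ± 0.20). For Sprr2d (1 of 2), S100a8 (1 of 2) and Smim3 (1 of 2) only some TPA arrays were above the limit. Plagl1 lost its call in 7 of the 8 fits that left out 1 array, all but the one without expanded replicate 2 (adjusted p up to 0.195), and Col6a1 in the one without TPA replicate 1 (adjusted p = 0.0742). Krt6a (0.60 ± 0.09) and Krt16 (0.75 ± 0.07) were higher, and Fosl1 (-1.28 ± 0.14) and Ccn1 (-1.53 ± 0.16) lower, in the expanded arrays. The count rested on single arrays, with 636 genes without expanded replicate 2, 560 without expanded replicate 3 and 568 without TPA replicate 1. It was 511 with only these 2 groups in the fit, and 64 in a test against a fold of 1.5.

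Of the 34 lists, 15 were shifted between expanded and TPA arrays by limma's camera, 9 higher and 6 lower. With an estimated correlation camera called 0 (6 at an unadjusted p under 0.05), and fry called 13. The AP-1 list was lower in the expanded arrays, with a median of -0.59 (adjusted p = 1.69e-18), and of 20 measured members 0 were higher and 15 lower (0 and 18 adjusted over the list alone). Btg2 (-1.16 ± 0.15) and Jun (-0.88 ± 0.12) were among them. The heat shock list was called in the same direction, with a median of -0.15 (adjusted p = 0.0048, and adjusted p = 0.213 with an estimated correlation), and of 8 measured members 0 were higher and 3 lower (0 and 3 adjusted over the list alone), with Dnajb1 at -0.45 ± 0.07. The stress and wound list was higher, with a median of 1.10 (adjusted p = 2.32e-06), and of 14 measured members 8 were higher and 1 lower (10 and 1 adjusted over the list alone). YAP/TAZ targets had a median of -0.18 (adjusted p = 8.24e-05), and of 20 measured members 0 were higher and 7 lower (1 and 8 adjusted over the list alone), with Gadd45a (-1.24 ± 0.14) and Rbms3 (-1.14 ± 0.13, above the background limit on 2 of 3 expanded arrays), an RNA-binding protein gene, lower. Clock genes had a median of -0.17 (adjusted p = 0.000862), and of 15 measured members 0 were higher and 4 lower (0 and 4 adjusted over the list alone), with Arntl at -1.46 ± 0.13. In the NRF2 list, of 14 measured members 6 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.13 (adjusted p = 0.000914) and Gsta4 at 1.52 ± 0.09. The adjusted p of these lists other than heat shock was 0.0867 with an estimated correlation. Single TPA arrays moved some of their medians. Without TPA replicate 1 the median was -0.07 for YAP/TAZ targets, 0.27 for NRF2 and -0.31 for clock genes, and without TPA replicate 2 it was -0.29 for YAP/TAZ targets and -0.03 for clock genes.

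S phase genes were higher in the expanded than in the TPA arrays, with a median of 0.33 (adjusted p = 4.88e-07, and adjusted p = 0.266 with an estimated correlation), and of 22 measured members 5 were higher and 0 lower (14 and 0 adjusted over the list alone). Rrm2 (0.93 ± 0.08) and Mcm5 (0.59 ± 0.09), a subunit of the replicative helicase, were higher. With signals raised to the background limit the S phase median was 0.29, and 1 of the higher members lay under it in both groups. Mitosis genes had a median of 0.18 (adjusted p = 0.0355, and adjusted p = 0.772 with an estimated correlation), but of 21 measured members 1 was higher and 0 lower (7 and 1 adjusted over the list alone), and the list did not pass with fry or without expanded replicate 3 or either TPA array (adjusted p up to 0.388). Its median was 0.31 without expanded replicate 2 and 0.11 without expanded replicate 3. Glycolysis and hypoxia genes had a median of 0.24 (adjusted p = 8.24e-05), and of 17 measured members 6 were higher and 0 lower (10 and 0 adjusted over the list alone), with Car9 higher by at least 0.99. In the unfolded protein response list, of 16 measured members 5 were higher and 1 lower (9 and 2 adjusted over the list alone), with a median of 0.28 (adjusted p = 0.0234) and Trib3 at 1.37 ± 0.10. Its median was 0.15 with signals raised to the background limit. With an estimated correlation the adjusted p of these last 2 lists was 0.341. SRF/MAL genes had a median of 0.23 (adjusted p = 0.00295, and adjusted p = 0.319 with an estimated correlation), and of 20 measured members 5 were higher and 1 lower (10 and 2 adjusted over the list alone). Actn1 (1.14 ± 0.08) and Cald1 (2.52 ± 0.29, above the limit on 1 of 2 TPA arrays) were higher and Srf itself lower (-0.56 ± 0.08).

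A further 4 lists were called between expanded and TPA arrays. Ribosome biogenesis genes had a median of 0.17 (adjusted p = 0.000346), and of 18 measured members 3 were higher and 0 lower (8 and 0 adjusted over the list alone). Infundibulum and upper follicle genes, whose cells the gate takes in, had a median of -0.50 (adjusted p = 0.00408), but of 10 measured members 0 were higher and 0 lower (0 and 0 adjusted over the list alone), and the list did not pass with fry. Without expanded replicate 3 its median was -0.29, and Krt79 was 7.51 in that array against 10.57 and 10.04 in the other expanded arrays. Krt79 was at -1.77 ± 0.81 (adjusted p = 0.281). The adjusted p of both lists was 0.361 with an estimated correlation. Respiratory chain genes had a median of 0.09 (adjusted p = 0.012, and adjusted p = 0.266 with an estimated correlation), and of 17 measured members 1 was higher and 0 lower (2 and 0 adjusted over the list alone). Wnt pathway genes had a median of -0.06 (adjusted p = 0.034, and adjusted p = 0.303 with an estimated correlation), and of 14 measured members 0 were higher and 1 lower (0 and 1 adjusted over the list alone), Wnt3 (-1.32 ± 0.12). The respiratory chain list did not pass without TPA replicate 2 (adjusted p = 0.15) and had a median of 0.16 without TPA replicate 1. The Wnt list did not pass without expanded replicate 1 or TPA replicate 1 (adjusted p up to 0.154), and had a median of -0.12 without expanded replicate 2. The 9 lists of other cell types had medians from -0.26 to 0.27 and did not pass. Under the background limit in both groups lay 9 of 10 macrophage and neutrophil, 8 of 10 pigment cell, 8 of 11 T cell and 7 of 9 Merkel cell members. For the other lists this ranged from 1 of 9 (sebaceous gland) to 5 of 10 (fibroblasts). Medians of lists mostly under the limit cannot show whether those cells changed.

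The differences of the expanded and the TPA arrays from control went the same way for most called genes. Both comparisons called 780 genes higher and 831 lower, and 10 in opposite directions. Independent lists of these sizes would share 99.2 and 105 genes. The log2 differences correlated across genes at r = 0.83, beside 0.45 (median) in 100 draws of unchanged groups simulated against the same controls. Their covariance was 0.136 beside 0.00705 in the simulation, a difference of 0.129. Genes are not independent replicates, so no p-value is given. The 3 control arrays do not split into parts of at least 2. Part of the excess of the shared calls and of r may therefore come from these arrays. The difference in covariance leaves out only the share that independent noise in these arrays would give. Anything common to all 3 control arrays stays in it. Of the 3559 genes called between TPA and control, 3031 (85.2%) had their expanded mean between the other 2 group means, beside 57.8% (median of 100 draws, highest 59.6%) with expanded arrays simulated as unchanged from control. The expanded difference was a median 0.54 of the TPA difference, with quartiles of 0.32 and 0.75, beside 0.03 in these draws. This ratio takes the arrays labelled control as its zero, and counted from the arrays labelled TPA it was 0.46, with quartiles of 0.25 and 0.68.

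A smaller set lay outside both other groups, with both comparisons of the expanded arrays past the threshold. There were 30 genes above both and 42 below both. Among the genes furthest above were Serpina3n (1.99 ± 0.14 against control, 0.89 ± 0.15 against TPA), a protease inhibitor, Serpinb3a (1.93 ± 0.16 and 0.89 ± 0.18) and P4ha3 (0.68 ± 0.16 and 1.77 ± 0.17), a collagen prolyl hydroxylase subunit. Among those furthest below were the protease Prss23 (-2.03 ± 0.12 and -1.53 ± 0.14), Ifi202b (-1.31 ± 0.12 and -1.31 ± 0.13) and Rnf19b (-0.82 ± 0.10 and -0.85 ± 0.11), a ubiquitin ligase gene. These genes were picked by size after the 2 comparisons had been made. No list was enriched in either set by Fisher's exact test over the 17097 genes, 2-sided (lowest adjusted p = 0.0740, the YAP/TAZ targets F3, tissue factor, and Igfbp3 among the genes below).

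**Figure D4:**
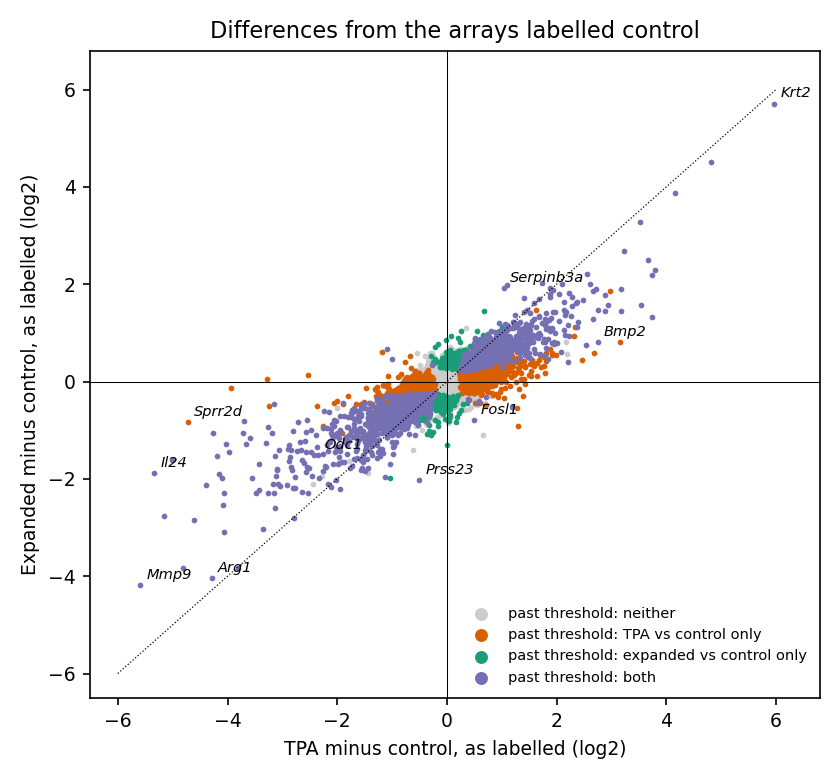
Log2 difference of each of 17097 genes between the expanded and control arrays (vertical axis) against that between the TPA and control arrays (horizontal axis), coloured by the comparisons in which the gene passed the threshold, with equal differences on the dotted line. Most genes called in both lie in the same quadrant and between the dotted line and the horizontal axis, as for Mmp9 (-5.60 in TPA and -4.19 in expanded arrays). Signals under the background limit are shown as measured.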

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

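The test of probe sets with no gene name was chosen after the data were examined. The comparisons by gene leave out the 15588 probe sets that carry no gene name, and these hold differences of their own. Between expanded and control arrays limma called 862 of them, 433 higher in the expanded arrays and 429 lower. Between TPA and control arrays it called 2061, 1301 higher in the TPA arrays and 760 lower. They drew notice because some were called higher than in the control arrays, in data outside the comparisons by gene. Between expanded and TPA arrays it called 592, 174 higher in the expanded arrays and 418 lower. By gene, 1960, 3559 and 1022 of 17097 passed in the same 3 comparisons, a larger share each time. No count of unnamed probe sets under the background limit is given. No explanation was tested for them.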

How the results depend on the processing

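The alternatives were planned, and each was run. Counts of genes past the threshold stayed within 1.5 times the reported ones under quantile normalization, median centring, the signal filter, the mean of a gene's probe sets, trended robust eBayes and array weights. With every probe set tested by itself they were 3872 (expanded and control), 8012 (TPA and control) and 2171 (expanded and TPA), with 3175 called by both treatments and r = 0.80. A test against a fold of 1.5 gave 173, 596 and 64, with 162 in both. For expanded and TPA the count was 511 with only these groups in the fit and 1650 at a threshold of 0.10. The numbers do not pair the arrays, and with a replicate block the counts were 1642, 2829 and 541, of which 1541, 2726 and 518 were shared with the reported genes. The cause of the fall to 541 was not tested. Leaving out 1 array gave 1261 to 2076 genes (lowest without control replicate 2), 2613 to 3344, and 560 to 922 (636 without expanded replicate 2, 560 without expanded replicate 3, 568 without TPA replicate 1), with fewer arrays in each fit. In all of these fits 1035, 1862 and 322 genes kept their call, and 0 changed sign. Genes called by both treatments numbered 1108 to 1476, and r was 0.79 to 0.83, whose spread was taken as the SD over these fits, 0.0173. Spearman's rho was 0.70. Where a TPA array is left out, the other is assumed to vary like the other groups.

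Camera with an estimated correlation called 0, 0 and 0 lists, against 13, 14 and 15, and fry called 15, 20 and 13. Leaving out 1 array gave 11 to 14, 12 to 14 and 13 to 16. Over all alternatives, list results were on the same side of the threshold in 1618 cases, weaker in 78 and stronger in 20, and named genes in 7934, 594 and 102. Among these same-side cases 43 list results and 25 gene results, counted over comparisons and alternatives, changed sign with neither value past the threshold. Sc5d reversed between TPA and control, to 0.32 (adjusted p = 0.202) with the mean of its probe sets, and the cause was not tested. The share of called genes that were higher went from 49.0% to 54.5% between TPA and control, and from 52.9% to 45.0% between expanded and TPA, with median centring. Signals near the top of the scale, such as Krt5, Krt14 and Krt6a, limit the differences that can be seen.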

Other observations

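The tests of suprabasal cells, of a batch and of a single mixing fraction, with its subset of dimmer genes and its simulated arrays, the simulation of unchanged expanded arrays and the background limit were chosen after the results were seen, and the phorbol ester genes were picked after the pattern was seen but before their own values were. Single genes of 4 further lists differed while these lists did not pass. Among junction genes, the desmosomal cadherin Dsc2 differed by -4.02 ± 0.16 and Ocln, the gene of the tight junction protein occludin, by at least 1.09 between TPA and control arrays. The list had a median of 0.04 (adjusted p = 0.828). Claudin gene Cldn4 differed by -1.98 ± 0.33 between expanded and control arrays (above the background limit on 1 of 3 expanded arrays), where the list median was 0.01 (adjusted p = 0.636). In the Notch list, with a median of -0.23 between TPA and control (adjusted p = 0.559), the receptor Notch1 (0.81 ± 0.08) and the target Hes1 (1.01 ± 0.16) were higher and the ligand Jag1 (-0.69 ± 0.07) was lower.

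Among p53 targets, Trp53inp1 (1.94 ± 0.19) and Sesn1 (1.20 ± 0.14) were higher in the TPA than in the control arrays, while Sesn2 (-1.31 ± 0.12) and the cell cycle inhibitor Cdkn1a (-0.41 ± 0.07) were lower. The list median was -0.25 (adjusted p = 0.322). Interferon response genes had a median of 0.07 (adjusted p = 0.388), with Psmb8, a subunit of the immunoproteasome, at 0.83 ± 0.09 and Irf9 at 0.61 ± 0.11. With signals raised to the background limit the interferon median was -0.03, as 7 of 14 members lay under it in both groups. Of the array controls, the one named for Gapdh had a mean of 4.68 and the bacterial dap control 3 rows before it 13.05, where the Gapdh gene itself was at 13.39. Of the 10 splits of the control and expanded arrays into 3 and 3, the real one gave 1960 genes and the highest other 0, so 1 split gave as many, and 10 splits are too few for a share under 0.05.

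Of 14 measured stress and wound genes, 11 were lowest in the arrays labelled TPA and highest in those labelled control, and Serpinb2 and Serpinb3a were among the others. More suprabasal cells in the control sort stay open, since the suprabasal genes went both ways (TPA minus control). Of 18 members 6 passed higher and 3 lower, with Krt1 (1.40) and Krt10 (1.46) higher and Tgm1 (-2.11) lower. Their median was 0.33, but its quartiles (-0.35 and 0.65) span 0, and with signals raised to the background limit it was 0.18. An exchange of the control and TPA labels may explain the pattern: 7 further genes known from phorbol ester treated or inflamed skin (Hmga1 was also picked but not measured) had a median of -0.55, with Odc1 (-2.35), Hmga2 (-2.82, above the background limit on 1 of 2 TPA arrays), Upp1 (-1.27), Tnfrsf12a (-0.31) and Cd44 (-0.24) past the threshold and Lcn2 (-0.55) and Saa3 (under the background limit in both groups) not. The mitosis (median -0.46, 11 of 21 lower), S phase (-0.21, 8 of 22) and cytokine lists (-0.30, 6 of 22), whose genes TPA is known to raise, were called lower in the arrays labelled TPA too. With an estimated correlation their adjusted p was 0.478, 0.45 and 0.381. The cytokine median was -0.17 without control replicate 1 and -0.03 with signals raised to the limit. The S phase median was -0.15 with signals raised to the limit. Against an exchange stands the AP-1 list, of which 14 of 20 members were higher in the arrays labelled TPA (adjusted p = 0.13 with an estimated correlation). The heat shock genes Hspa1b (0.98) and Dnajb1 (0.41) were higher there too, so that a handling response in AP-1 is not excluded. The series design gives the same group sizes as the labels, 3 control and 2 TPA mice. Both come from 1 series record, so their match cannot decide. A sorting or amplification batch that follows the groups was not tested, since the labels hold 0 batch fields that span more than a single group, and scan dates were not used. An effect of TPA itself stays open as untested.

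The expanded arrays lay between the other groups for 3031 of 3559 genes (85.2%, beside 59.6% at most with simulated unchanged arrays). Mixed cells or RNA of the other groups could place them there, but 72 genes lay outside both, where arrays simulated as a mixture in every gene gave 6 at most in 100 draws, which argues against mixing as the whole cause. A single mixing fraction of the other groups left 48.5% of 167 strongly different genes more than 3 SE away (best fraction 0.73), and 47.3% of the 129 genes under a log2 signal of 11. Independent noise in the shared control arrays alone gave a covariance of 0.00762 at most in the simulation, beside 0.136. A trait common to all 3 control arrays was not simulated. A biological response that both treatments share stays open, as does an order of the groups that follows a batch.

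The clock list was called higher in the TPA than in the control arrays, with 8 of 15 members past the threshold (adjusted p = 0.13 with an estimated correlation). A different time of day at harvest would likely move the activators Arntl, Clock and Npas2 against their outputs, but Arntl (1.32) and Npas2 (0.51) were higher, as 4 of 8 outputs were (median 0.29). The median of the activators, 0.60, is the value of Clock itself, which did not pass (adjusted p = 0.0665) and has 1 of 4 probe sets called in the opposite direction. The rise of Arntl and Npas2 beside 4 outputs argues only against a shift that moves activators and outputs in opposite directions. The outputs Dbp (0.15), Per2 (0.04), Per3 (0.14) and Ciart (-0.14) did not pass. A shift of phase that raises activators and some outputs together was not tested and stays open. A change of the whole clock with treatment, or with the state of the cells, stays open and was not tested.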
